A study of Homo sapiens with 6 samples.

How the data were processed

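Samples were grouped by their labels into miR-31 mimic and control mimic, 3 arrays each, with the replicate numbers of the labels. For each array the deposited export holds a signal, a detection score, a bead standard deviation and a bead number for each of 48803 probes. Per the file headers the signal is the average bead intensity of a probe on a linear scale, and the authors exported it with BeadStudio, per the submitters' processing notes, which give no version. Its median and upper quantiles differed from array to array, so it was taken as not normalised between arrays. The deposited detection score runs up to 1, and 1 minus the score was used as a detection p-value. The authors' deposited series value table was also in intensity units, with a median of 55.6 on every array. Set against the exports, the column of 1 array was equal to its export, and the other columns held that array's values in the rank order of their own export, so the table is quantile-matched to 1 array, on a linear scale, with no centring; the step that made it is not given in the sources used here. Bead standard deviation and bead number (other columns of the deposited exports) served for quality only: the standard error over beads was 3.79 to 4.61% of the signal for a median detected probe. No column of other samples was present in the tables used.

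Genes were named from the platform annotation supplied with the value table, whose probe names differ from those of the exports. The probe names were joined by finding, for each probe, the same values on all 6 arrays to 4 decimals, once the exports had been mapped as above: 48803 of 48803 probes joined one to one, and 0 did after shuffling. The annotation gave 1 symbol for 28098 probes, several for 13 and none for 20692. Of those with 1 symbol, 28059 had a gene identifier in the RefSeq gene table of GRCh38.p14, which was used for names alone, and they cover 18852 genes. Probes with several symbols or none were named nowhere. Sources used here name no genome build, so no coordinates are printed. The dose given in the labels' protocol belongs to an experiment with another cell line and inhibitor and was not used here.

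Signals were processed in limma 3.58.1 under R 4.3.3 with neqc, which corrects the background by normexp, with the background taken from the detection p-values, adds an offset of 16, normalises by quantiles and takes log2. Fold changes are therefore on a scale that understates changes of dim genes. A probe was tested if its detection score was above 0.99 on at least 3 of the 6 arrays, and 19992 probes passed, 15816 of them with a gene. The tested probe with the highest mean represented a gene, which gave 11946 genes; 3010 had another tested probe. Among the 1454 called genes with another tested probe, every other probe had the same sign for 1211. Values were compared with lmFit and eBayes (with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Rose and fell are used for genes past it. An exact permutation test of 3 arrays against 3 cannot go below 0.1 and was not used. Where a gene was detected on no array of a group, the fold is given as a bound: the mean of the other group against the mean, per array, of the higher of its own signal and the lowest detected signal. Such detection on no array held for 109 tested genes with the miR-31 mimic and 21 with the control mimic.

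Before the data were examined, 26 gene lists were written from general knowledge, and older symbols in them were updated through the RefSeq table; this update was planned but applied only once list results had been seen, and it changed no list call. Each was tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the 26 lists), and also with an estimated correlation and with fry, which asks whether the genes of a list move one way without setting them against other genes. With an estimated correlation 0 lists passed, and 1, the published targets, at an unadjusted p under 0.05. That setting also refers the camera statistic to the few residual degrees of freedom of the arrays, not to those over all genes. At an equal correlation it is therefore the stricter test. A call lost in that setting is not by itself a sign of correlation among members. For the published targets the estimate was -0.02, below the preset, yet the unadjusted camera p went from 1.46e-05 to 0.0072. For the fibroblast markers it was 0.01, and p went from 0.0072 to 0.0545. The interferon, NF-kB and cholesterol lists had estimates of 0.25, 0.12 and 0.24. For these lists the higher correlation and the fewer degrees of freedom were not told apart. Named genes were fixed by a rule at the same time: the 12 largest rises and 12 largest falls among named genes past the threshold whose groups did not overlap, up to 4 members of each list with the smallest adjusted p, and a set of genes discussed in work on miR-31. Some genes and lists covered by these rules are not reported here, though every list entered the adjustment. Alternatives covered background correction, offset, normalisation between arrays, the value table, the detection filter, the probe rule, the variance model, array weights, the replicate number as a block, the threshold and leaving out each array; the closing section gives their effect. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for joining and plotting.

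The steps were tested on simulated data made from the real arrays' means and residual spread, with 66 or 67 genes changed by each of 3 known folds in the comparison of the miR-31 mimic with the control mimic. Of the genes changed 2-fold, 95.5% were called, of those changed 1.5-fold 68.7%, and of those changed 1.23-fold 30.3%; 4 of 134 calls among 12791 genes were false (3%). By camera, a list made of changed genes was found shifted and a list of unchanged genes was not. Every member of the first list was lowered 2-fold, unlike the mixed real lists, and noise was drawn for each probe independently. The outcome therefore does not show how camera treats mixed lists or correlated genes. The simulated noise was revised, and then revised again, after its results had been seen: the first version recovered too few of the genes changed 2-fold to meet the stop set for it, and the second recovered fewer genes at each fold than the version given here, whose noise is drawn from residuals of the normalised real arrays. The shares called therefore depend on that choice and describe the last version only.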

Results

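Gene expression was measured in OVCAR-8, a cell line from a high-grade serous ovarian carcinoma, after transfection with a synthetic double-stranded RNA that mimics the microRNA miR-31 or with a control mimic based on a nematode microRNA with little similarity to human ones. Cells were harvested 48 h after transfection, and total RNA was hybridised to Illumina bead arrays, 3 with the miR-31 mimic and 3 with the control mimic. The labels call the replicates biological but do not say whether they were separate transfections, so p-values measure the spread between these arrays only. The median probe signal ran from 54.6 to 58.0 over the 6 arrays, each probe was read by a median of 40 or 41 beads, and 38.7 to 41.6% of the 48803 probes were detected. The number of arrays limits the precision. The design asks which transcripts change when miR-31, described as under-expressed in ovarian cancer, is raised. The arrays do not measure mature microRNAs, so the level of miR-31 itself was not analysed here. No untransfected array is among the 6, so each difference is one between 2 mimics.

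With the miR-31 mimic, transcripts of the membrane protein TMEM109, the oxidase AOX1, the kinase STK40, the BRCA1-A and BRISC complex member BABAM2, the E2F partner TFDP2 and the endosomal protein LITAF were among the 12 largest falls by the rule for named genes. Transcripts of the chemokines CXCL8 and CXCL2, the secreted protein FAM3C, the AP-1 subunit FOS and the cyclin-dependent kinase inhibitor CDKN2D were among the 12 largest rises. TMEM109 was 5.53-fold lower (log2 change -2.47, SE 0.07, n = 3 arrays per group, limma adjusted p = 1.29e-12), and CXCL8 was 3.48-fold higher (log2 change 1.80, SE 0.13, adjusted p = 1.24e-08). Large falls outnumbered large rises: 226 genes fell at least 2-fold and 27 rose at least 2-fold. Where the values were offset more strongly or not background-corrected, which compresses the changes of dim genes, 92 to 117 fell and 10 to 13 rose at least 2-fold. Of 11946 genes tested, 5033 (42.1%) passed the adjusted p threshold of 0.05, of which 2423 rose and 2610 fell, and most of these changes were small, with a median absolute log2 change of 0.39. That balance depended on the scaling: with median scaling 2750 rose and 2351 fell, and with cyclic loess 2002 rose and 2982 fell. At least 1.5-fold changes were called for 1136 genes, 298 higher and 838 lower. That number was 618 to 692 under the same alternatives. The 3 arrays of each group lay apart from those of the other for 51.3% of genes, against 10% by chance, and correlations between arrays were 0.9956 to 0.9971 within groups and 0.9836 to 0.9869 between them.

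**Figure D1:**
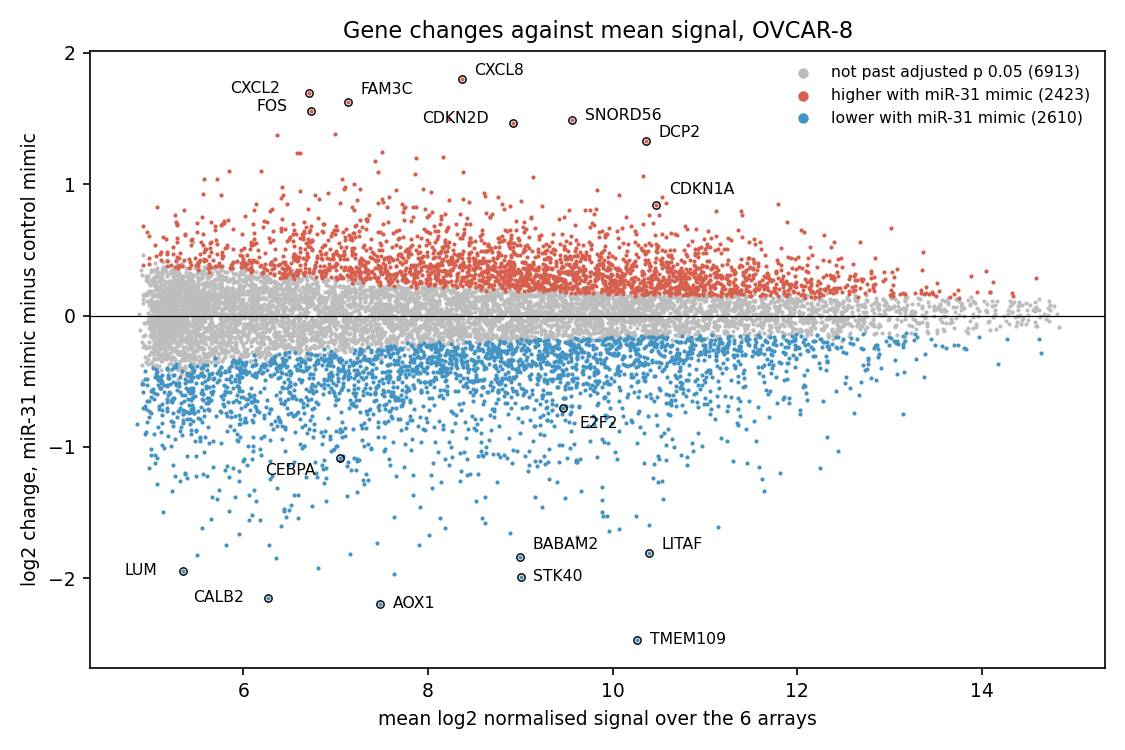
Log2 change of each of the 11946 tested genes (vertical axis, miR-31 mimic minus control mimic) against its mean log2 normalised signal over the 6 arrays (horizontal axis). Red points mark the 2423 genes that rose, blue points the 2610 that fell and grey points the rest; the points farthest from 0 are mostly falls, with TMEM109 at -2.47 and CXCL8 at 1.80, and LUM was below detection with the miR-31 mimic, so that its point shows a fitted value.

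Among the 12 largest falls by the rule for named genes, AOX1 was 4.58-fold lower, the muscle actin ACTC1 3.90-fold lower, the citrate transporter SLC13A5 3.80-fold lower, the interferon-inducible GTPase GBP1 3.60-fold lower, BABAM2 3.57-fold lower and TFDP2 3.52-fold lower, and LITAF fell by 1.81 on the log2 scale, with limma adjusted p of 6.17e-09 or smaller. Other tested probes of BABAM2 (log2 change -1.86), GBP1 (-1.71) and TFDP2 (-1.58) went the same way. The matrix proteoglycan LUM was detected on all 3 control arrays and on none with the miR-31 mimic, and was at least 2.40-fold lower (adjusted p = 1.15e-08). The pregnancy-specific glycoprotein PSG3 was likewise at least 2.57-fold lower (adjusted p = 1.54e-07); this family has near-identical members, so the transcript behind the probe is uncertain. The probe used for the calcium-binding protein CALB2 fell (log2 change -2.15, adjusted p = 5.23e-09), but its other tested probe stood at 0.25 (SE 0.17) and did not pass. Among the largest rises, CXCL2 was 3.24-fold, FAM3C 3.08-fold, FOS 2.93-fold and the RAS-induced membrane protein TMEM158 2.82-fold higher. The probe for the small nucleolar RNA gene SNORD56 was 2.81-fold and CDKN2D 2.76-fold higher. The cytokine genes IL1B and IL12A were both 2.60-fold higher, the decapping enzyme DCP2 2.51-fold, the translational regulator CPEB3 2.37-fold and MATCAP2 2.36-fold higher, and the largest adjusted p among these 12 was 6.60e-06.

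Of 37 tested genes reported elsewhere as miR-31 targets, 21 fell with the mimic, 5 rose and 11 did not pass, with a median log2 change of -0.32. By camera this list was shifted down (adjusted p = 1.89e-04), a call lost with an estimated correlation (adjusted p = 0.187). The estimate was -0.02, below the preset 0.01, so correlation among members does not account for that loss. The setting with an estimated correlation also leaves the test fewer degrees of freedom. The study of these samples is known to have looked at 3 members, E2F2, STK40 and CEBPA, so their place in the list is not independent evidence of its direction. STK40, a kinase described as a negative regulator of NF-kB signalling, was 3.97-fold lower (log2 change -1.99, SE 0.07, adjusted p = 9.47e-12). CEBPA, a transcription factor of myeloid and adipocyte differentiation, was 2.12-fold lower (adjusted p = 6.71e-07), and the cell cycle transcription factor E2F2 was 1.63-fold lower (adjusted p = 1.48e-06). The Notch regulator NUMB fell 1.96-fold, the WNT antagonist DKK1 1.74-fold and the kinase SRC 1.61-fold; the other tested probes of NUMB and DKK1 stood at log2 changes of -0.96 and -0.98. RDX and LATS2 were 1.24-fold and 1.26-fold lower, and LATS2 no longer passed without the miR-31 mimic replicate 3 (log2 change -0.28, adjusted p = 0.056). The integrin ITGA5 rose 1.26-fold (adjusted p = 6.22e-04), and RHOA (log2 change 0.05), MMP16 (0.14) and PPP2R2A (0.01) did not pass. The brightest probe of MPRIP rose 1.23-fold, but its other probes ran from -0.59 to 0.42, and the mean of all its probes (0.04) did not pass. FZD3 was not detected on any array.

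With E2F2, STK40 and CEBPA left out of the published targets, the median was -0.27 (camera adjusted p = 0.00252), an alternative chosen after seeing the data. In the full list, with E2F2, STK40 and CEBPA included, 21 members fell and 6 rose when adjusted over the list alone.

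**Figure D2:**
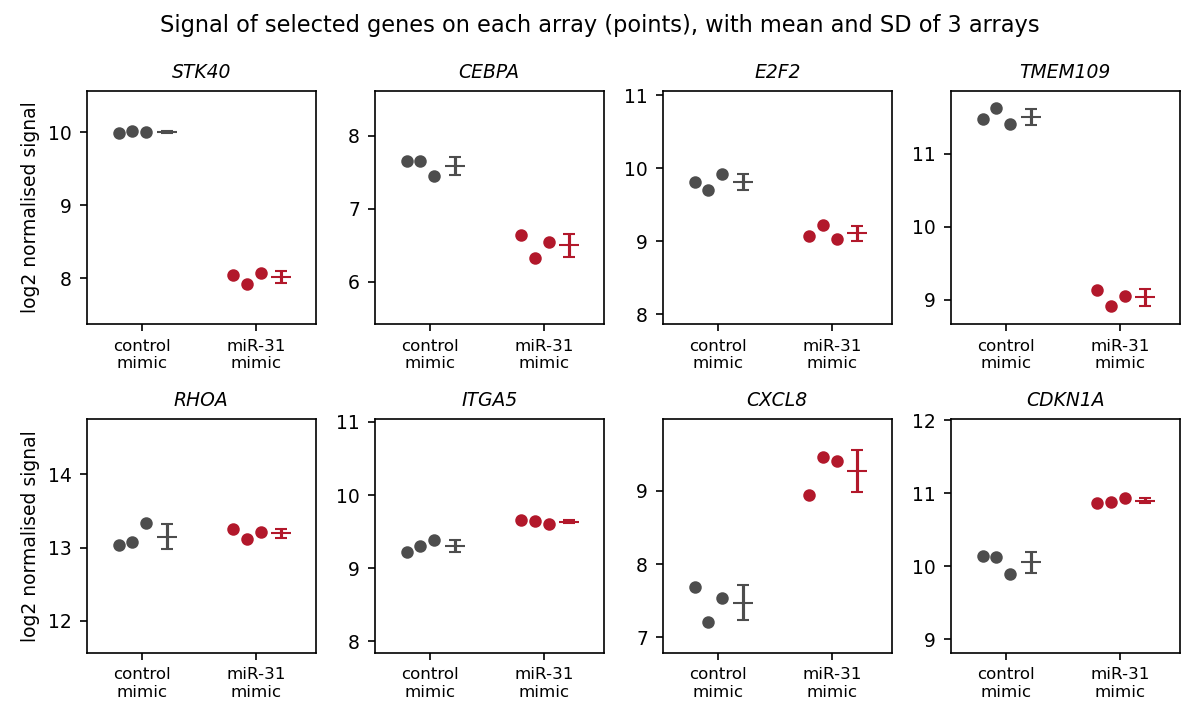
Log2 normalised signal of 8 genes on each of the 3 control mimic arrays (grey points) and the 3 miR-31 mimic arrays (red points), with the mean and SD of 3 arrays beside the points and a vertical axis for each gene that does not start at 0. STK40, CEBPA, E2F2 and TMEM109 lie lower and ITGA5, CXCL8 and CDKN1A higher on all 3 miR-31 mimic arrays, while the 2 groups overlap for RHOA.

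Interferon response genes were lower with the miR-31 mimic than with the control mimic by camera (adjusted p = 1.29e-07), a call lost with an estimated correlation (adjusted p = 0.451). Of 32 tested members 21 fell, among them IFI35 by 2.61-fold, the immunoproteasome subunits PSMB9 by 2.87-fold and PSMB8 by 1.94-fold (log2 changes of -1.05 to -0.37 on its other probes), and IFI27 by 1.96-fold; 10 did not pass. The single member that rose was OAS1 (log2 change 0.91), named here after its value was seen. The median log2 change was -0.58, or -0.51 with the 2 members below detection in a group set to their bound. Adjusted over the list alone, the counts were the same, 21 and 1.

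NF-kB and inflammatory genes went the other way, with 14 of 22 tested members higher, 1 lower and 7 not passing (median log2 change 0.33). The camera adjusted p was 3.45e-04, and the call was lost with an estimated correlation (adjusted p = 0.451). CXCL8 and CXCL2 led, followed by IL1B and by TNF, which was 2.35-fold higher (log2 change 1.23, SE 0.10, adjusted p = 9.22e-08). The member that fell was NFKB1 (log2 change -0.28), named after its value was seen. Adjusted over the list alone, 14 rose and 1 fell.

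Genes of cholesterol and fatty acid synthesis were mostly lower, with 14 of 23 tested members down, 1 up and 8 not passing, and a median log2 change of -0.27. The camera adjusted p was 0.00191, and the call was lost with an estimated correlation (adjusted p = 0.693). The fatty acid desaturase SCD fell 2.39-fold (adjusted p = 1.13e-06) and the isoprenoid enzyme IDI1 2.00-fold, while the sterol reductase DHCR7 fell 1.41-fold and the desaturase FADS1 1.39-fold. The member that rose, PMVK (log2 change 0.29), is named after its value was seen. Adjusted over the list alone, 14 fell and 1 rose.

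Of the lists fixed as markers of other cell types, 4 of 6 tested fibroblast and stromal markers fell. The list median was -0.63 (camera adjusted p = 0.0375), a call lost with an estimated correlation (adjusted p = 0.451). The estimate was 0.01, equal to the preset at that rounding, while the degrees of freedom were fewer. PDGFRB was 2.16-fold lower and ACTA2 and COL1A1 were each 1.54-fold lower beside LUM, which was below detection with the miR-31 mimic; adjusted over the list alone the number was again 4. The call of the list was also lost without each control mimic array in turn (medians of -0.53, -0.73 and -0.57 and adjusted p = 0.171, 0.0829 and 0.221 without replicates 1, 2 and 3), and with detection required on all 6 arrays (adjusted p = 0.0954) or eBayes without trend (adjusted p = 0.0752), where the median stayed at -0.63. With no detection filter the median itself went to -0.01 (adjusted p = 0.226). Among 5 tested leukocyte markers CD68 alone fell, by 1.19-fold. Its other probes ran from -0.03 to 0.08, and with the mean of a gene's probes its call was lost (log2 change -0.07, limma adjusted p = 0.428). Among 4 tested endothelial markers ESAM fell 1.87-fold and ENG 1.33-fold. Neither list passed (adjusted p = 0.807 and 0.505). Of 12 tested serous and epithelial markers 5 fell and 2 rose (list adjusted p = 0.148): the folate receptor FOLR1 was 2.73-fold, MUC1 2.11-fold, KRT7 1.45-fold and CD24 1.35-fold lower; the other probes of MUC1 ran from -1.11 to -0.49 on the log2 scale, and that of CD24 stood at -0.26.

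Genes of the cell cycle changed in both directions. Among 27 tested regulators of the RB and E2F pathway, 7 rose and 10 fell. CDKN2D and the phosphatase CDC25A rose (2.76-fold and 1.89-fold), while TFDP2 and the ubiquitin ligase subunit SKP2 fell (3.52-fold and 1.82-fold). The cyclin-dependent kinase inhibitor CDKN1A rose 1.79-fold on the probe used (adjusted p = 9.36e-08), and its other probe stood at a log2 change of 0.21. Of 42 replication genes 8 rose and 5 fell, with CDT1 1.42-fold, ORC1 1.41-fold and GINS2 1.33-fold higher and MCM2 lower (log2 change -0.59). MCM7, named after its values were seen, did not pass on the probe used (log2 change -0.06). Its other tested probes stood at -0.12 and 1.93, the latter with a limma adjusted p of 3.50e-10 over the tested probes. Of 41 mitotic genes 13 rose and 6 fell, with CCNA2 1.56-fold, KIF2C 1.33-fold and PLK1 1.32-fold higher and CCNB2 1.32-fold lower. Of 29 apoptosis genes 9 rose and 7 fell, with BAK1 1.68-fold higher and TRADD and CASP2 1.89-fold and 1.37-fold lower; the other probes of CASP2 ran from -0.27 to 0.09 on the log2 scale. None of these lists was shifted by camera (adjusted p = 0.807, 0.807, 0.553 and 0.553 in the order given). In the replication list and in the RB and E2F list the median (-0.02 and -0.08) and the mean (0.02 and -0.01) lay close to 0, and in the replication list they differ in sign.

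Adhesion and matrix genes held more falls than rises, as did all tested genes in the main run (2610 fell and 2423 rose). None of the lists given here passed in that run. Of 29 tested integrin and adhesion genes 11 fell and 3 rose (list adjusted p = 0.148), with the integrin-linked kinase ILK 1.53-fold, VCL 1.41-fold, ITGA3 1.36-fold and EPCAM 1.29-fold lower. Of 29 matrix and EMT genes 8 fell and 6 rose (adjusted p = 0.804), with the secreted protein SPARC and the transcription factor SNAI2 2.11-fold and 2.10-fold lower and PLAUR and LAMA5 1.74-fold and 1.54-fold higher. Of 22 TGF-beta and BMP genes 10 fell and 4 rose (median -0.19, adjusted p = 0.111). ID3 was 2.40-fold, the ligand TGFB2 2.05-fold and TGFBI 1.68-fold lower, while the co-receptor TGFBR3 was 1.56-fold higher. That list passed without the miR-31 mimic replicate 1 (adjusted p = 0.0416) or replicate 3 (0.0387).

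The remaining signalling and stress lists did not pass. Of 25 RAS and MAPK genes 7 rose and 6 fell (adjusted p = 0.456), with FOS, HRAS (1.62-fold; log2 change 0.43 on its other probe) and PHLDA1 (1.51-fold) higher and MET 1.91-fold lower. Of 24 WNT genes 7 fell and 3 rose (adjusted p = 0.553), with FZD2 1.38-fold lower beside DKK1 and with FZD7 and LEF1 1.48-fold and 1.37-fold higher on the probes used, their other probes standing at log2 changes of 0.09 and 0.13. Of 27 hypoxia genes 7 rose and 7 fell (adjusted p = 0.876). ANKRD37 was 2.82-fold and HIF1AN, an inhibitor of HIF, 1.72-fold lower, and P4HA2 and ADM were 1.37-fold and 1.35-fold higher; the other probes of P4HA2 stood at 0.22 and 0.47 on the log2 scale. Of 26 unfolded protein and stress response genes 6 rose and 5 fell (adjusted p = 0.851), with XBP1 1.69-fold, CALR 1.68-fold and HSPA5 1.33-fold lower and VLDLR 1.55-fold higher.

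Among 19 tested genes of microRNA biogenesis and the silencing complex, 6 rose and 2 fell (median 0.08, adjusted p = 0.362). AGO2, which carries microRNAs to their targets, was 1.70-fold higher (adjusted p = 4.28e-08), TNRC6A was 1.46-fold and TNRC6C 1.90-fold higher, and SND1 was 1.62-fold lower. TNRC6C was detected on 2 of the 3 control arrays. DICER1 was 1.34-fold higher on the probe used, and its other 2 probes ran from about 0 to 0.31.

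Housekeeping and other reference lists moved little. Of 15 tested housekeeping genes 12 did not pass, HPRT1 among them (log2 change 0.11), and the list median was -0.01 (adjusted p = 0.937). B2M, which is also part of the antigen-presenting complex, fell 1.34-fold (adjusted p = 2.05e-04). TBP was 1.14-fold higher and IPO8 1.14-fold lower, and each lost its call in several of the alternatives. Of 37 ribosomal protein genes 2 rose (RPS24 and RPS7, 1.29-fold and 1.22-fold) and 4 fell, RPL13 (1.26-fold) and RPS23 (1.29-fold) among them (list adjusted p = 0.807). The other probes of RPS24 (log2 change -0.07) and RPL13 (0.12) stood on the other side of 0, and with the mean of a gene's probes both calls were lost (log2 change 0.15, adjusted p = 0.0639 for RPS24 and -0.11, adjusted p = 0.183 for RPL13). Of 34 oxidative phosphorylation genes 6 fell and 2 rose (camera adjusted p = 0.937). SDHD was 1.44-fold, ATP5MC1 1.27-fold and NDUFV1 1.18-fold lower in that list. NDUFA8 was 1.14-fold higher, a call lost with eBayes without trend (limma adjusted p = 0.0518). The median of that list (0.01) and its mean (-0.02) differ in sign, as do those of the leukocyte markers (0.06 and -0.06). Near the miR-31 locus, CDKN2B and MTAP were 1.18-fold and 1.13-fold lower (limma adjusted p = 0.0215 and 0.0283), both calls being lost in some alternatives. HACD4 and KLHL9 (log2 change 0.18 and -0.14) did not pass in the main run. HACD4 passed with the mean of a gene's probes (limma adjusted p = 0.0437) and with array weights (0.0336), and KLHL9 with cyclic loess (0.0234). HACD4 had no other tested probe, so its own change was still 0.18 with the mean of probes. This list of 7 tested genes did not pass either (camera adjusted p = 0.553). MIR31HG, the host transcript of miR-31, was not analysed here. Over the 21 lists that did not pass, counts of rises or falls adjusted over the list alone differed from those over all genes by at most 3.

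**Figure D3:**
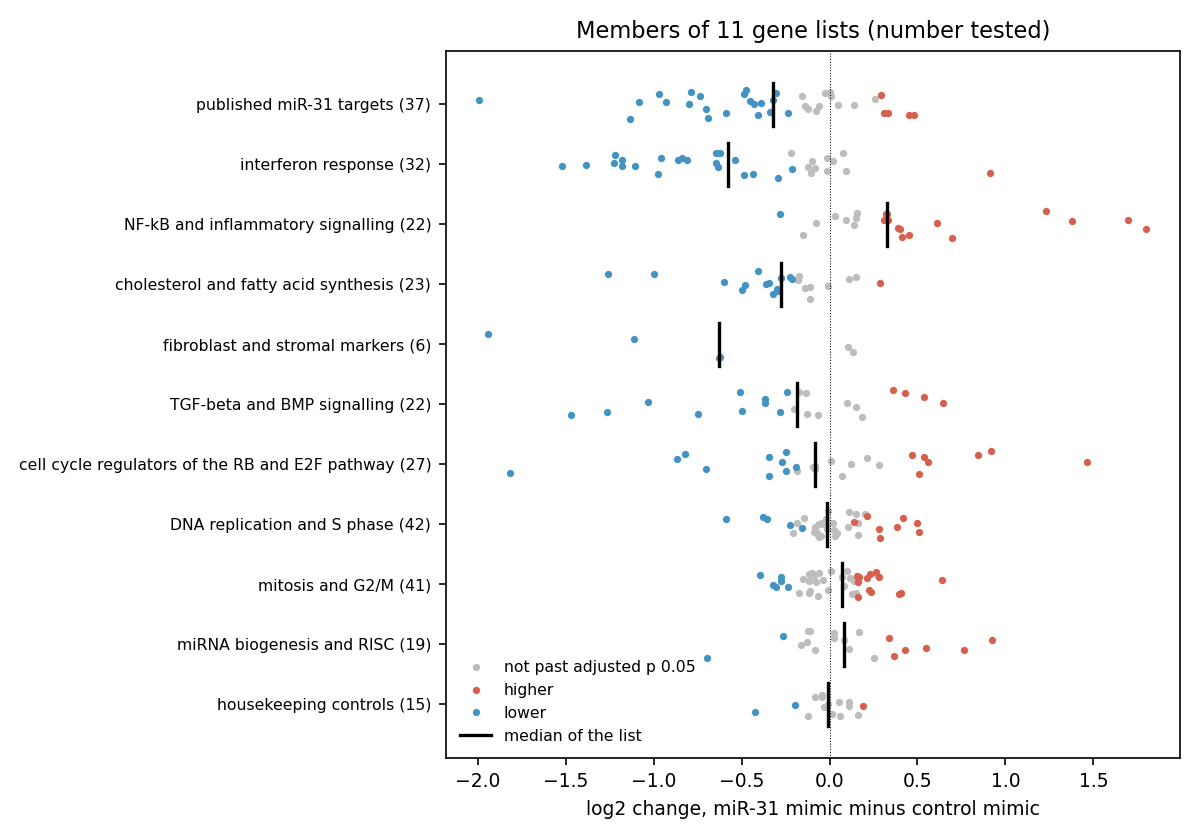
Log2 change (horizontal axis, miR-31 mimic minus control mimic) of each tested member of 11 gene lists, with the number tested in brackets. Red and blue points are members that rose and fell at adjusted p under 0.05, grey points did not pass, and black bars are list medians, which run from -0.63 for fibroblast and stromal markers to 0.33 for NF-kB and inflammatory signalling.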

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

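Of 4176 detected probes with no gene in the annotation used, 986 passed an adjusted p of 0.05 over those probes alone, 578 higher and 408 lower with the miR-31 mimic than with the control mimic. They stood out because they carry a difference between the groups in data that the gene comparisons do not use. A larger share passed among the tested genes, 5033 of 11946 (42.1%). No gene names were given to the probes without one.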

How the results depend on the processing

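No called direction of a named gene or list turned in any alternative, but the balance of all called genes did: falls outnumbered rises in the main run (2610 to 2423), and rises outnumbered falls with median scaling (2750 to 2351); removal of E2F2, STK40 and CEBPA from the published targets, and of leading genes from 3 added lists, was chosen after seeing the data. The number of genes past the threshold was 4220 to 4726 without 1 of the 6 arrays, against 5033. The count changed at least 1.5-fold was 619 without normexp, 622 with normexp and an offset of 50 without controls, 692 with the offset at 50 and 618 with the value table, against 1136. In the same order, 92, 92, 117 and 94 genes fell at least 2-fold, against 226, and 10, 10, 13 and 10 rose, against 27. These settings add more to each signal before the log or leave the background in it, which by construction compresses changes of dim genes. Median scaling moved the median log2 change of all genes from 0.01 to 0.047 and cyclic loess to -0.029, and the share of calls that were rises from 48.1% to 53.9% and 40.2%. With an estimated correlation 0 lists passed camera, 1 at an unadjusted p under 0.05, against 5 with the preset one, and the published targets lost their call (adjusted p = 0.187 with a median of -0.32, which this setting cannot change, against 1.89e-04, and 2.50e-05 to 0.00252 under its other alternatives); by fry 16 lists passed, in a test that does not set a list against other genes. Replicate numbers did not pair the arrays (correlations of deviations 0.10, -0.09 and -0.13), and with the replicate block 4726 genes passed. Both used the numbers in the sample descriptions, 1 to 3 in each group; the titles of the control arrays carry other numbers, so the check and the block depend on that choice, and whether further control arrays were made is not given in the sources used here. Over all alternatives, calls of named genes were lost 17 times with 1 array left out and 12 times otherwise and gained 4 times, mostly for changes near 0.2 such as those of TBP, IPO8, MTAP and CDKN2B; the cause was not tested. A test of genes with miR-31 seed sites was not run because no 3' UTR sequences were used here, and a slide block was not run because the files used name no slides. Signal over background limits the dimmest genes, for which changes are understated.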

Other observations

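The tests of probe choice and of other splits of the arrays were written after their results had been seen, and those of probe choice replaced earlier forms with other labels. The lists of antigen presentation, NRF2, BRCA1-A complex and small nucleolar RNA genes were drawn up because of genes among the larger changes and are not independent of them, and the lists of other microRNAs' targets were added when some members' changes had been seen. Adjusted p-values of these 8 added lists are over the 8.

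Antigen presentation genes were lower with the miR-31 mimic than with the control mimic. By limma, 19 of 26 tested fell and 0 rose, 0 also at an unadjusted p under 0.05, with a median log2 change of -0.43. HLA-DMA (-1.67) and HLA-DMB (-0.99), which load class II peptides, the class I-like MR1 (-1.21), the proteasome activator PSME2 (-0.77) and the loading factor TAPBP (-0.76) are among them. The camera adjusted p was 6.51e-09, and 0.0231 with an estimated correlation. Without HLA-DMA and the members shared with the interferon response list, 15 of 22 fell (median -0.41, camera adjusted p = 1.10e-06, and 0.0442 with an estimated correlation). Only 4 genes were left out in this way. Whether the remaining ones also respond to interferon was not tested, so this does not set antigen presentation apart from the interferon response. HLA genes are close paralogs and polymorphic, so single HLA values are uncertain. The counts use 1 probe per gene: PSME1, counted as a fall (-0.61), had another probe past the threshold at 0.55.

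Targets of NRF2, the transcription factor of the antioxidant response, were lower as well. By limma, 15 of 24 tested fell and 0 rose, 1 at an unadjusted p under 0.05, with a median log2 change of -0.22 (camera adjusted p = 4.11e-05, and 0.0334 with an estimated correlation). NQO1 (-1.20), the cystine transporter SLC7A11 (-0.70) and the glutathione synthesis enzyme GCLC (-0.58) fell, as did AKR1C3 (-1.54), which has close paralogs. Without NQO1 and AKR1C3 the median was -0.21 (adjusted p = 0.0012, and 0.0737 with an estimated correlation). Of 41 small nucleolar RNA genes 18 rose and 3 fell (median 0.21, camera adjusted p = 0.0118, and 0.221 with an estimated correlation). Whether their probes read the mature RNAs or longer transcripts that hold them was not tested. In the BRCA1-A complex BABAM2 (-1.84) and BABAM1 (-1.52) fell, and the other 4 tested members stood between -0.02 and 0.08 (list adjusted p = 0.0946).

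Falls of at least 2-fold outnumbered rises 8.37 to 1. If the scaling of arrays had made the excess by a shift of the zero line, another scaling would bring that ratio toward 1. With median scaling and cyclic loess, which replace the quantile step, its lowest value was 8.38. These moved the median log2 change of all genes only from 0.01 to 0.047 and -0.029. A shift that all these scalings share would therefore not show. An excess made by dim genes would vanish at high signal. Among genes with a mean log2 signal above 9 there were 241 falls and 78 rises of at least 1.5-fold, a ratio of 3.09. At the same fold there were 838 falls and 298 rises over all tested genes. The ratio of 8.38 argues against the choice among these scalings as the source, and that of 3.09 against dim genes at 1.5-fold. Repression by the miR-31 mimic may account for the excess, as a hypothesis that the seed-site test, not run here, would have to meet.

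The lower interferon response genes do not rest on 1 array: the list median stayed between -0.60 and -0.46 with each of the 6 arrays left out. These falls were not confined to probes near background, but how far the list median rests on such probes stays open. The 16 members brighter than the median gene had a median of -0.25 with a 95% bootstrap interval of -0.64 to -0.10, and 9 of them fell and 0 rose, against 12 falls among the 16 dimmer ones; the median alone met the bound of -0.2 set before the test as counting against background probes, but the interval, added once the median had been seen, spans it. Induction of interferon by the control mimic, itself a double-stranded RNA, cannot be told apart from repression by the miR-31 mimic, because no untransfected array was analysed here. Of 29 probes for interferon genes 3 were detected on all control arrays, and of those 0 were undetected on all miR-31 mimic arrays.

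AGO2, TNRC6A, TNRC6B, TNRC6C and DICER1, noticed together after their values were seen, were higher with the miR-31 mimic (log2 changes 0.77, 0.55, 0.37, 0.92 and 0.43). A mimic that displaced the cells' own microRNAs could also release their targets. Both groups received a mimic, so only a difference in displacement between the 2 mimics could show here. Of the lists of published targets of 4 other microRNA families, 1 was shifted up: let-7 targets, with 11 of 27 up and 3 down (median 0.19, adjusted p = 0.0226, and 0.125 with an estimated correlation), DICER1 being one of them. Targets of the miR-17 family (median -0.13, camera adjusted p = 0.419), miR-21 (-0.02, 0.466) and the miR-16 family (0.06, 0.308) were not shifted. A larger displacement by the miR-31 mimic than by the control mimic is therefore neither excluded nor borne out, and displacement by both alike was not tested. AGO2, TNRC6B and TNRC6C had a single tested probe each, so there was no choice among tested probes, and no second probe to check them. That these 3 genes stood above 0 by more than 2 standard errors restates their calls. Probe choice stays open for TNRC6A and DICER1. There 0 of 4 other tested probes stood that far above 0, and 1 of them lay below the probe used by more than 2 standard errors. Both genes kept their calls with the mean of a gene's probes, which includes the probe used.

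Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 5033 genes by limma; the highest of the others was 0, with 62 to 238 genes at an unadjusted p under 0.05 against 5910. Each other split puts arrays of both groups on each side, so the group difference widens its spread and lowers its calls in advance. Those splits therefore give no measure of chance, and a share under 0.05 cannot be had from 10 splits.

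Among 963 genes with more than 1 probe past the threshold, 65 had probes called in opposite directions. For the adenylate kinase AK4 the probe used stood at 0.25 and another at -2.43.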
